A study of Mus musculus with 8 samples.

How the data were processed

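The samples were mouse embryonic stem cells (mESC), pluripotent cells that grow indefinitely in culture, of wild-type (WT) and METTL5 knockout (KO) genotype at passages 5 to 10. METTL5 is the methyltransferase that, with its partner TRMT112, places N6-methyladenosine on 18S ribosomal RNA. Total RNA was sequenced from 2 WT and 2 KO libraries (RNA-seq), and ribosome-protected mRNA fragments from 2 WT and 2 KO libraries (Ribo-seq). Per the labels' protocols, the RNA-seq material was taken from nearly confluent cells, and the footprints came from the monosome part of a sucrose gradient. The same protocols name a small RNA library kit for the sequencing libraries, a ligation method that keeps the strand of the RNA. The series calls the replicates biological and does not say how many KO clones were used, so p-values measure the spread between these libraries.

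Each library came as a table of 23845 mouse gene symbols. The submitters' processing notes name Bowtie2 2.3.4.3, RSEM and the mm10 build, and the alignment and strand settings are not given in the sources used here. Per the file headers, the deposited tables hold RSEM expected counts, which are estimates that split reads shared between genes. Per the file headers, they also hold deposited TPM and FPKM values, and the gene and effective lengths. The expected counts were rounded to whole numbers and used in the tests, the deposited TPM entered 1 alternative, and the deposited FPKM values were not used. Total expected counts were 211353 and 219567 in the WT RNA-seq libraries, 152195 and 173389 in the KO RNA-seq libraries, 10466185 and 8401463 in the WT Ribo-seq libraries, and 9322662 and 11487964 in the KO Ribo-seq libraries. In a library, 3 counts corresponded to between 13.7 and 19.7 CPM in RNA-seq and between 0.261 and 0.357 CPM in Ribo-seq, which is counting error only. CPM values, counts scaled to the same library total, were used for levels.

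Each comparison set KO against WT. RNA-seq and Ribo-seq libraries were fitted apart with the edgeR 4.0.16 quasi-likelihood test (robust glmQLFit), TMM factors, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment, and a gene was called below an adjusted p of 0.05. Translational efficiency, footprints relative to the RNA-seq counts of the same gene, was tested as the interaction of assay and genotype in 1 edgeR fit over all 8 libraries, on genes that passed the filter in both assays. Standard errors (SE) of log2 fold changes were derived from the F statistics. Replicates were compared with a chi-square over genes. The statistic per degree of freedom was 10.3 for WT and 3.87 for KO RNA-seq and 26.1 for WT and 22.9 for KO Ribo-seq, so no pair of replicates was closer than sampling noise.

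Before the data were examined, 26 gene lists were fixed, covering pluripotency states, embryonic and extraembryonic lineages, fibroblasts, translation, ribosome biogenesis, RNA methylation, stress responses, metabolism, the cell cycle, imprinted and Y-linked genes. They were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as companions. Lists with at least 3 tested members were tested, a minimum chosen after seeing the data. Named genes followed a rule fixed in advance. It always took Mettl5, Trmt112, Fbxw7, Myc, Atf4, Pou5f1, Sox2 and Nanog, then the 8 largest increases and 8 largest decreases among called genes with a mean count of at least 50 whose KO and WT libraries did not overlap, leaving out names of clones, microRNAs, snoRNAs, accessions and pseudogenes. From each called list it took the 3 members with the smallest p, and from each other list up to 2. For translational efficiency, non-overlap was judged on log2(CPM + 0.5) differences. Ssb, Krt8, Spon1, Ftl1, Col4a1, Col4a2 and the interferon-related genes were added after their values were seen.

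The agreement of RNA-seq and footprint changes was described by correlations across genes, which are not independent replicates, with 2000 bootstrap draws, and by Fisher's exact test of the overlap of calls. Gene positions, strands and exon overlaps came from GENCODE M21 on GRCm38, the assembly behind mm10, and 22724 of the 23845 symbols matched. Chromosomes of genes came from the RefSeq table of the same assembly. The steps were tested on simulated counts with 200 changed genes. All genes were given the same dispersion, with no link between same-numbered libraries, so recovery and false calls in the real data may differ. For Ribo-seq (12107 genes), 97.9% of genes changed 4-fold and 44.0% of those changed 2-fold were recovered, with 2.82% false calls. For RNA-seq (1873 genes) the shares were 85.9% and 15.2%, and for translational efficiency (1268 genes) 85.1% and 14.8%.

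Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), another scaling, no filter, a mean count of at least 50, a replicate block, a test against a 1.2-fold change, joint fits, a length correction and leaving out each library in turn. Chromosome medians removed, TMM within each assay and the removal of genes overlapping an opposite-strand gene were added after seeing the data. R 4.3.3 and Python 3.11.15 were used.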

Results

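RNA-seq and Ribo-seq were collected from WT and METTL5 KO mouse embryonic stem cells, with 2 libraries per genotype and assay, to compare mRNA levels, ribosome occupancy and translational efficiency without the enzyme. The footprint tables held 8401463 to 11487964 counts per library and 11810 to 12368 genes with at least 10 counts. The RNA-seq tables held 152195 to 219567 counts and 1714 to 2089 such genes. Abundant mRNAs were nearly empty in the RNA-seq tables. The 100 genes with most footprints took 21.5% to 23.9% of the footprint counts but 0.692% to 1.06% of the RNA-seq counts. Eef1a1, the translation elongation factor, stood at 11139 to 16742 CPM in footprints and at 209 to 644 CPM in the RNA-seq tables, and Pou5f1, the core pluripotency factor, had 3 to 18 counts per RNA-seq library. Rn45s, the ribosomal RNA precursor, took 7.58% to 15.2% of the footprint counts, and 3.33% and 7.99% of the WT against 0.638% and 1.02% of the KO RNA-seq counts.

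Footprints on Mettl5, the targeted gene, fell about 10-fold in the KO. Its level was 43.6 ± 3.37 CPM in WT and 4.43 ± 0.504 CPM in KO (SD, n = 2 each), a log2 fold change of -3.27 (SE 0.22, adjusted p = 0.00131). In the RNA-seq tables Mettl5 was at 499 ± 144 CPM in WT and 287 ± 43.1 CPM in KO, with a log2 fold change of -0.88 that did not pass the test (adjusted p = 0.126; 0.0147 without WT replicate 1). Mettl5 lies on the minus strand of chromosome 2, from 69871198 to 69885615 (GRCm38). Its 3' end overlaps by 169 bp of exons with the 3' end of Ssb, on the plus strand from 69861562 to 69871846, which encodes the La RNA-binding protein. Ssb fell in the RNA-seq tables from 200 ± 51.3 to 12.7 ± 9.86 CPM (log2 fold change -4.05, SE 0.64, adjusted p = 0.00658), while its footprints, 545 CPM in WT and 382 CPM in KO, did not pass the test (-0.50, SE 0.15, adjusted p = 0.126). Footprints on Trmt112, the partner of METTL5, stood at 145 ± 33.6 CPM in WT and 143 ± 40.1 CPM in KO (log2 fold change -0.02, adjusted p = 0.975).

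**Figure D1:**
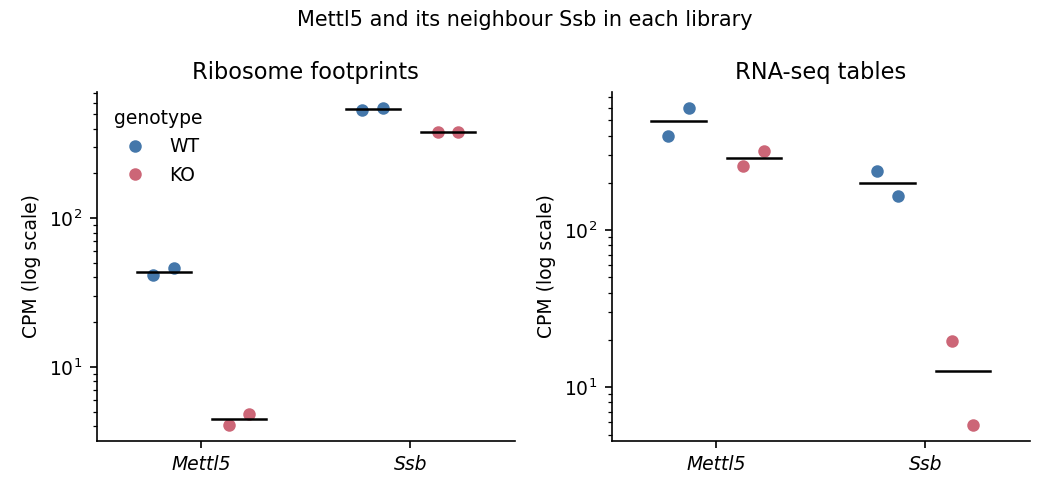
CPM of Mettl5 and Ssb on a log scale in each library, with footprints on the left and RNA-seq tables on the right; points are libraries and bars are means of 2. Mettl5 footprints fell from 43.6 to 4.43 CPM, whereas in the RNA-seq tables Ssb fell from 200 to 12.7 CPM.

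Outside Mettl5, the footprint comparison asked which genes had more or fewer footprints in the KO. Footprint counts follow both the mRNA level and the ribosomes per mRNA, which this comparison does not separate. Igf2, an imprinted growth factor, Igfbp5, a binding protein of insulin-like growth factors, and Wls, the carrier of secreted Wnt proteins, rose. The keratins Krt8 and Krt18 rose about 4-fold, and Cubn and Dab2, genes of the yolk sac endoderm, fell. The pluripotency factors Pou5f1, Sox2 and Nanog did not pass the test. Of 12315 genes tested, 301 were called, 225 higher and 76 lower in KO, and 2387 had an unadjusted p below 0.05. With the replicate number as a block, 2960 genes were called, 1566 higher and 1394 lower. The labels do not say that a number marks a shared day, so the fit without a block is reported. Deviations of same-numbered footprint libraries from their group means correlated by 0.424, and same-numbered WT and KO libraries share a tag in their deposited names. If the tag marks a shared day, the 301 calls are too few. Genes given as not passing in footprints did not pass in the fit without a block, which does not show that they were unchanged.

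Igfbp5 rose from 0.811 ± 0.474 to 11.7 ± 4.40 CPM (log2 fold change 3.81, SE 0.46, adjusted p = 0.00907), and Igf2 from 1.55 ± 0.515 to 21 ± 11.7 CPM (3.76, SE 0.51, adjusted p = 0.0151). Fras1, an extracellular matrix protein, rose from 0.847 ± 0.0189 to 9.86 ± 0.453 CPM (3.54, SE 0.33, adjusted p = 0.00238). Enpp2, the enzyme autotaxin that makes lysophosphatidic acid, rose from 3.85 ± 1.58 to 35.7 ± 1.40 CPM (3.20, SE 0.28, adjusted p = 0.00238). Arxes1 (3.19), Fndc3c1 (3.09), the guanylate-binding protein gene Gbp2b (2.77) and Wls (2.73) rose by the log2 fold changes in parentheses. Among genes with a mean count of at least 50, clone names left out, the largest decrease after Mettl5 was that of Cubn, an endocytic receptor, from 90.7 ± 35.7 to 15.8 ± 4.16 CPM (-2.51, SE 0.30, adjusted p = 0.00907). The muscle gene Myom2 (-2.16), the proteoglycan gene Srgn (-2.11), the metallothionein gene Mt3 (-1.99), the receptor gene Robo4 (-1.78), the endocytic adaptor gene Dab2 (-1.74) and the homeobox gene Crxos (-1.71) also fell.

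Pou5f1, Sox2, Nanog, Fbxw7, Myc and Atf4 did not pass the test. Log2 fold changes were 0.30 for Pou5f1 (adjusted p = 0.36), 0.05 for Sox2 (0.914) and 0.01 for Nanog (0.980). Fbxw7, a ubiquitin ligase subunit that targets MYC for degradation, was at 8.78 ± 0.384 CPM in WT and 10.2 ± 0.276 CPM in KO (log2 fold change 0.23, SE 0.22, adjusted p = 0.629). Myc was at 115 ± 53.9 and 73.3 ± 21 CPM (-0.65, SE 0.33, adjusted p = 0.333), and Atf4, the effector of the integrated stress response, at 52.2 ± 2.83 and 53.1 ± 5.24 CPM (0.04, adjusted p = 0.923). The count of called genes was 761 without WT replicate 1, 505 without WT replicate 2 and 189 without KO replicate 2. Of the 36 named genes called, 14 lost the call when some library was left out, among them Igf2, Mt3 and Tagln.

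**Figure D2:**
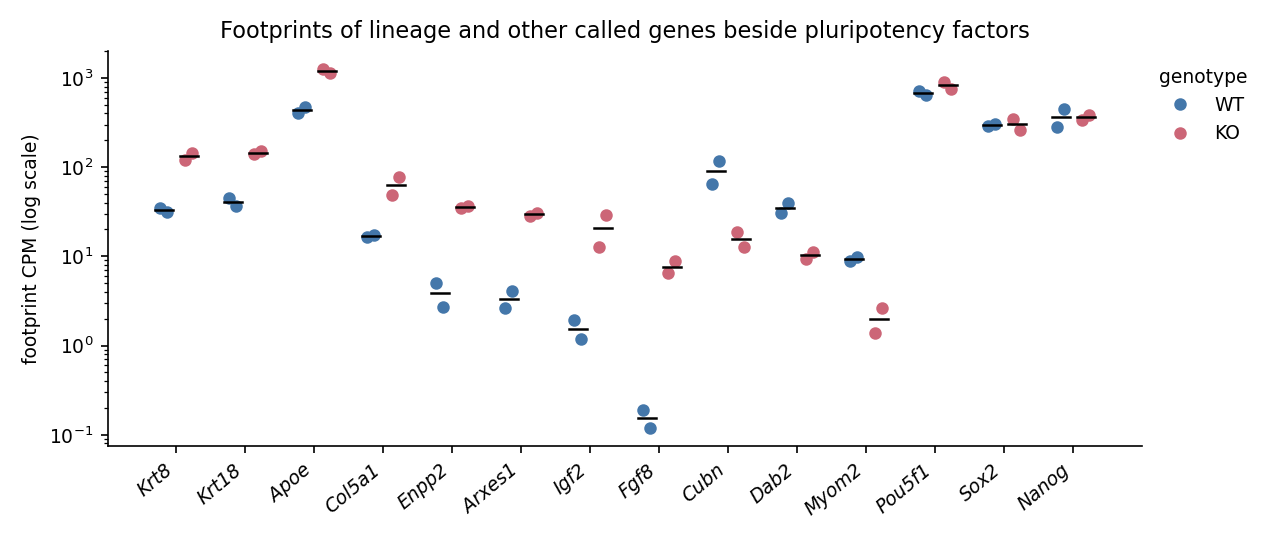
Footprint CPM on a log scale for called genes and for the pluripotency factors; points are libraries and bars are means of 2 per genotype. Krt8 rose from 33.1 to 132 CPM and Cubn fell from 90.7 to 15.8 CPM, while Pou5f1, Sox2 and Nanog overlapped or lay close between genotypes.

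Marker lists of several cell types had positive medians in KO footprints. Of 15 tested fibroblast markers, 3 rose (9 adjusted over the list alone), and the median log2 fold change was 1.80 (camera adjusted p = 7.56e-10; adjusted p = 0.559 with an estimated correlation). The fibroblast median was 1.12 without KO replicate 2 and 1.06 among genes with a mean count of at least 50. The collagen Col5a1 rose from 16.9 ± 0.819 to 63.5 ± 20.1 CPM, Col3a1 had 9 counts in WT against 135 in KO, and the actin-binding protein gene Tagln rose by 1.84. On log2(CPM + 0.5), the fibroblast list differed by a median of 0.66 between the WT libraries, -0.46 between the KO libraries and 1.15 between KO and WT. In the same order, the medians were 0.13, -0.30 and 0.999 for mesoderm, 0.11, -0.17 and 0.37 for trophoblast, 0.52, 0.45 and 0.72 for formative, -0.22, -0.20 and -0.97 for endoderm and 1.34, 0.91 and 0.82 for two-cell-like genes. Of 12 mesoderm and primitive streak markers, 3 rose (6 rose and 1 fell adjusted over the list alone), with a median of 1.12 (camera adjusted p = 6.74e-05; adjusted p = 0.559 with an estimated correlation). Without WT replicate 1 the mesoderm median was 1.82. All 3 were nearly absent in WT. Fgf8 had 3 WT and 161 KO counts, a ratio of 48.7 with an exact counting interval of 16.4 to 238. T, the brachyury factor, had 5 and 71 counts (ratio 12.9, interval 5.27 to 40.9), and Lhx1 3 and 54 (16.3, interval 5.29 to 81.6). These intervals pool the libraries of a genotype and leave out the spread between them. T and Lhx1 each lost their call in 3 of 15 alternatives. Among genes with a mean count of at least 50, which leaves Fgf8, T and Lhx1 out, the mesoderm median was -0.58 (camera adjusted p = 0.0536).

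Of 13 trophoblast markers, the keratins Krt8, Krt18 and Krt19 rose by 2.01, 1.86 and 1.24 (5 rose and 2 fell adjusted over the list alone). The list median was 0.45 (camera adjusted p = 0.00202; adjusted p = 0.580 with an estimated correlation; 0.0726 by camera without KO replicate 2; median -0.17 among genes with a mean count of at least 50). The trophoblast median was 0.75 without WT replicate 1, 0.01 without WT replicate 2 and 0.13 without KO replicate 2, so it hung on single libraries. Of 16 genes of formative and primed pluripotency, 2 rose (7 adjusted over the list alone), Car14 by 1.73 and Fgf15 by 1.27, and 15 had positive fold changes. Their median was 0.73 (camera adjusted p = 2.60e-07; adjusted p = 0.588 with an estimated correlation), and it was 1.24 without WT replicate 1 and 0.48 without KO replicate 1. Of 4 tested two-cell-like genes none was called (median 0.84, camera adjusted p = 0.0350; adjusted p = 0.667 with an estimated correlation), and the camera adjusted p was 0.180 without WT replicate 2 (median 0.25) and 0.0748 without KO replicate 1. Without WT replicate 1 the median was 1.55.

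Endoderm markers went the other way. Of 16 tested, 4 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -1.22 (camera adjusted p = 1.27e-08; adjusted p = 0.559 with an estimated correlation). Cubn, Dab2 and the basement membrane collagens Col4a1 (-1.63) and Col4a2 (-1.28) fell, and Apoe, the lipid carrier, rose from 441 ± 48.6 to 1207 ± 86.2 CPM (1.46, SE 0.17, adjusted p = 0.00739). Of 24 imprinted genes, 5 rose (9 adjusted over the list alone). Igf2, the antisense RNA Kcnq1ot1 (1.09) and Gnas (0.79) had the smallest p. The imprinted median was 0.51 (camera adjusted p = 7.08e-06, and adjusted p = 0.559 with an estimated correlation). Of 20 germline genes, Tex19.1 fell (-0.89) and Rpl10l rose (0.87), with 2 lower and 1 higher adjusted over the list alone. The germline median was -0.36 (camera adjusted p = 0.0222; adjusted p = 0.817 with an estimated correlation; 0.462 by camera without WT replicate 2 and 0.0722 without KO replicate 1). It was -0.24 with chromosome medians removed (camera adjusted p = 0.0439), and Tex19.1 and 5 other tested members lie on chromosomes 6, 8 or 11. It was -0.68 without WT replicate 1, -0.19 without WT replicate 2 and -0.64 without KO replicate 2.

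Ribosome biogenesis genes and translation factors had small negative list medians, with no member called in the fit without a replicate block. Of 51 ribosome biogenesis genes, 47 had negative fold changes and none was called, over all genes or adjusted over the list alone, with a median of -0.24 (camera adjusted p = 1.51e-06; adjusted p = 0.667 with an estimated correlation). Without WT replicate 2 the median was -0.38. The smallest p values were those of the helicase Ddx47 (-0.72, adjusted p = 0.0563), Nob1 (-0.63, 0.0686), which matures the 18S end, and Polr1a (-0.71, 0.0828), the large subunit of RNA polymerase I. Of these 51 genes, 13 lie on chromosomes 6, 8 or 11, whose footprints were lower as a whole, and with chromosome medians removed the list median was -0.24 (camera adjusted p = 5.14e-06). Of 45 translation factors none was called by either adjustment (median -0.13, camera adjusted p = 0.0135; adjusted p = 0.667 with an estimated correlation; 0.321 by camera without WT replicate 1). The translation factor median was -0.07 without WT replicate 1 and -0.24 without WT replicate 2. Eif5b, the subunit joining factor, had -0.63 (adjusted p = 0.0748), Abce1 -0.54 and Eif4g3 0.72. MYC targets (30 tested, none called by either adjustment) had a median of -0.19 (camera adjusted p = 0.0241; adjusted p = 0.667 with an estimated correlation; 0.265 by camera without WT replicate 1, 0.0539 without KO replicate 2, and 0.147 with chromosome medians removed). Their median was -0.32 without WT replicate 2. Their smallest p values were those of Cdk4 (0.56), Phb2 (-0.63) and Shmt1 (-0.58).

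The m6A machinery list (23 tested) held 1 called gene, Mettl5 itself, by either adjustment, with a median of -0.10 (camera adjusted p = 0.0222; adjusted p = 0.559 with an estimated correlation; 0.0655 by camera without WT replicate 1 and 0.0786 without KO replicate 2). The m6A median was 0.002 without WT replicate 1 and -0.16 without KO replicate 1. Mettl16 (-0.60) and Hnrnpa2b1 (-0.44) did not pass the test. Integrated stress response genes (30 tested, none called by either adjustment) had a median of 0.28 (camera adjusted p = 0.0222; adjusted p = 0.817 with an estimated correlation; 0.321 by camera without WT replicate 1 and 0.181 without KO replicate 2). The stress response median was 0.18 without WT replicate 1. Cth (0.82), Sesn2 (0.59) and Stc2 (0.97) had their smallest p values. Of 30 G2 and M genes, the spindle checkpoint gene Mad2l1, on chromosome 6, fell (-0.80), also adjusted over the list alone, and the median was -0.10 (camera adjusted p = 0.0385; adjusted p = 0.667 with an estimated correlation). With chromosome medians removed Mad2l1 was at -0.42 and lost its call (adjusted p = 0.224), as it did without KO replicate 1 (0.0870) and KO replicate 2 (0.154). The list call was lost without WT replicate 2 (0.135), KO replicate 1 (0.0748) and KO replicate 2 (0.0653).

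The other 11 lists were not called, with camera adjusted p values from 0.0659 to 0.912. Some were called when a library was left out, namely neuroectoderm (0.0253), ribosomal proteins (0.00720) and histones (0.0110) without WT replicate 1, glycolysis (0.0400) without WT replicate 2, cholesterol synthesis (0.0408) without KO replicate 1, and neuroectoderm (0.0239), p53 targets (0.0459) and histones (0.00201) without KO replicate 2. Core pluripotency genes (18 tested) had a median of 0.02, with 0 called over all genes and 2 higher and 4 lower adjusted over the list alone; Fgf4 had 0.74 (adjusted p = 0.0547) and Zfp42 -0.58 (0.0904). Of 20 naive pluripotency genes, Tfcp2l1 rose (0.76; 3 higher and 2 lower adjusted over the list alone; median 0.06). Of 9 neuroectoderm markers, Sox11 rose (1.34), with 3 higher and 1 lower adjusted over the list alone. The neuroectoderm median was 0.64 (camera adjusted p = 0.0659), 0.54 without WT replicate 1 and 0.25 without KO replicate 1. Of 18 immediate early and heat shock genes, Jun rose (1.13), also adjusted over the list alone (median 0.03). No member was called by either adjustment among 79 cytosolic ribosomal proteins (median 0.07), 67 nuclear subunits of oxidative phosphorylation (0.08), 48 replication-dependent histones (0.10), 26 p53 targets (0.12), 20 glycolysis genes (0.11), 23 cholesterol synthesis genes (-0.03) and 6 Y-linked genes (0.09). The ribosomal protein median was 0.24 without WT replicate 1 and -0.13 without WT replicate 2. The core pluripotency and Y-linked lists had a positive median and mean and a camera direction of lower. Of the 13 mitochondrially encoded genes, 0 were among the symbols of the tables.

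**Figure D3:**
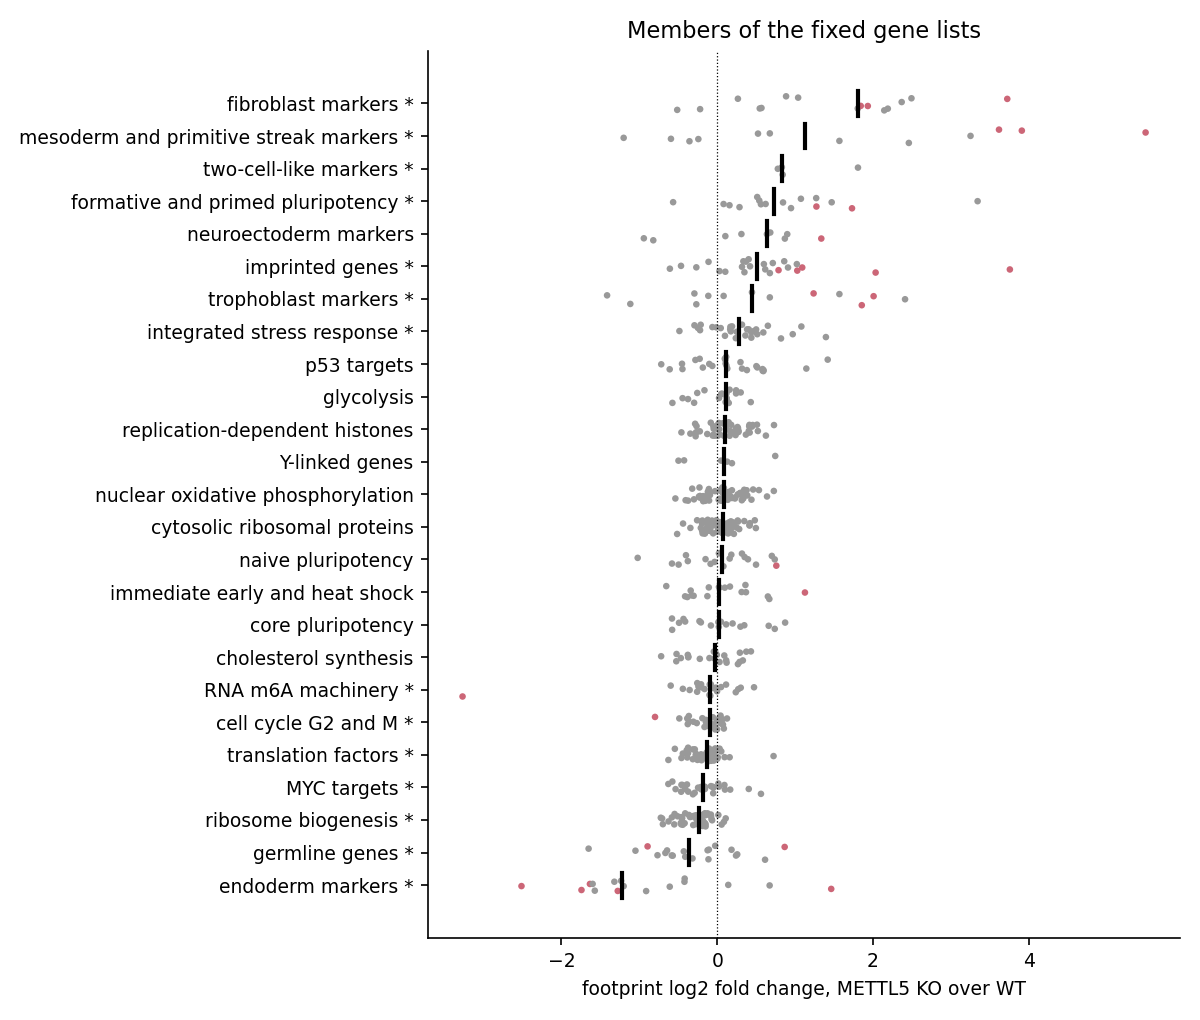
Footprint log2 fold change, KO over WT, of each tested member of the fixed lists; points are genes, red points are called over all genes, black bars are list medians, and a star marks a list called by camera with the preset correlation. Fibroblast markers have the highest median (1.80) and endoderm markers the lowest (-1.22).

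Footprint changes also differed by chromosome, a pattern chosen for description after the values were seen. The median log2 fold change was -0.38 over 536 genes of chromosome 6 (bootstrap interval -0.41 to -0.35), -0.22 over 643 genes of chromosome 8 (-0.26 to -0.18) and -0.25 over 999 genes of chromosome 11 (-0.27 to -0.23). On chromosome 6, 83.0% of genes had negative fold changes. The medians of the other autosomes and the X chromosome lay between -0.02 and 0.10. These 3 chromosomes carried 17.7% of the tested genes and 47 of the 76 genes called lower, Myom2, Mt3, Col4a1 and Mad2l1 among them. With chromosome medians removed, 228 genes were called, 190 higher and 38 lower.

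**Figure D4:**
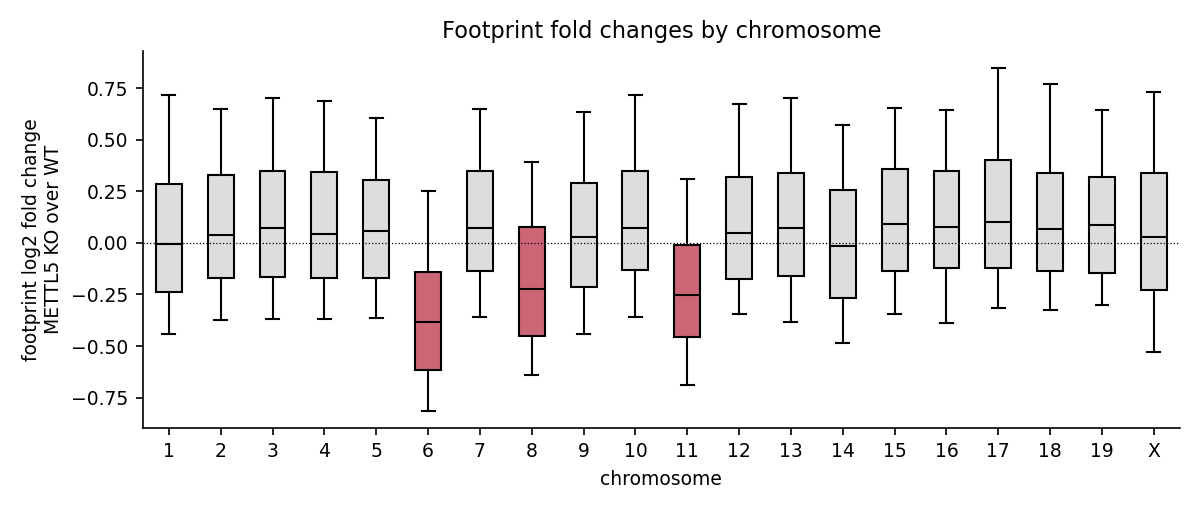
Footprint log2 fold change, KO over WT, of the tested genes of each chromosome; boxes span the quartiles with the median, whiskers reach the 10th and 90th percentiles, and chromosomes 6, 8 and 11 are in red. The medians of chromosomes 6, 8 and 11 are -0.38, -0.22 and -0.25.

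The strand setting behind the RNA-seq counts is not given in the sources used here, so the values below are those of the table entries with these names. In the RNA-seq tables, Xist, the noncoding RNA of X inactivation, rose from 796 ± 15.2 to 2547 ± 51.4 CPM (log2 fold change 1.58, SE 0.20, adjusted p = 0.00415), and Rtl1, an imprinted retrotransposon-derived gene, from 247 ± 104 to 1086 ± 79.2 CPM (2.03, SE 0.33, adjusted p = 0.00665). Rn45s fell from 56585 ± 32998 to 8299.9 ± 2715 CPM (-2.88, SE 0.45, adjusted p = 0.0106), and Tmf1, a Golgi protein gene, fell from 903 ± 324 to 211 ± 1.24 CPM (-2.19, SE 0.31, adjusted p = 0.00415). Of 44 cytosolic ribosomal protein genes, 5 fell. Of 2087 genes tested, 133 were called, 77 higher and 56 lower, and 482 had an unadjusted p below 0.05.

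Peg3os, an antisense transcript of the imprinted Peg3 locus, rose by 1.48, Masp2 by 1.45, Abt1 by 1.33, Cd84 by 1.27, Rhbdd2 by 1.27 and Gfer by 1.26. Klk14 (-2.06), Scn2b (-2.01), Xkrx (-1.92), Myoz3 (-1.84) and Rpph1 (-1.79), the RNA of ribonuclease P, fell. Of 44 ribosomal protein genes tested, 5 fell (14 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.47e-06; adjusted p = 0.356 with an estimated correlation). Rpl32 (-2.70) and Rpl3 (-1.84) were among them. Eef1a1 fell too (-1.42, adjusted p = 0.0214). The 100 genes with most footprints took 1.03% and 1.06% of the WT against 0.750% and 0.692% of the KO RNA-seq counts. Ribosomal protein genes were not separated from others in this share. Other abundant mRNAs named here were mostly lower. Npm1 (-1.42), Atp5a1 (-1.35), Ncl (-0.61), Gapdh (-0.48) and Atp5b (-0.44) were lower and Slc2a1 (2.13) and Gspt1 (1.44) higher, none passing the test. Slc2a1 had only 2 and 11 counts in WT. Fold changes were negative for 11 and positive for 3 of 14 translation factors, and negative for 7 and positive for 2 of 9 ribosome biogenesis genes. The fall was thus not particular to ribosomal protein genes. Actb stood at 137 and 120 CPM in WT against 195 and 137 CPM in KO RNA-seq. The other 14 lists with at least 3 tested members were not called (camera adjusted p 0.0762 to 0.811). Among their members Tdgf1, a pluripotency-associated coreceptor, fell (-2.76, adjusted p = 0.0490), and Tagln (3.86) and the cystine transporter gene Slc7a11 (1.14) rose. Tdgf1 had only 20 and 15 counts in WT and 2 and 2 in KO, and lost its call in 10 of 15 alternatives. Tagln had 3 and 0 counts in WT and 24 and 14 in KO, and lost its call in 3 of 14. Pou5f1 (-1.98, adjusted p = 0.0907) and Nanog (-0.84, adjusted p = 0.151) did not pass the test, and Fbxw7, Myc, Atf4 and Sox2 had too few counts to be tested.

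Of the 133 genes called in RNA-seq, 40 overlapped exons of a gene on the other strand, against 579 of the 2087 tested. Masp2, a complement protease gene that rose from 256 ± 59.4 to 747 ± 127 CPM, had 0.434 CPM of footprints, while Tardbp, whose exons it overlaps by 1817 bp on the opposite strand, had 347 CPM of footprints and 65.3 CPM (WT) and 24.3 CPM (KO) in the RNA-seq tables. Gm15441, antisense to Txnip over 606 bp, had 1378 CPM (WT) and 408 CPM (KO) in the RNA-seq tables and 0.136 CPM in footprints, and Txnip had 294 CPM of footprints. Other called genes went the other way, such as Serbp1, with 1438 CPM of footprints against 0.0993 CPM for Il12rb2 on the other strand. Over 2522 genes with an opposite-strand exon overlap of at least 100 bp, the RNA-seq level correlated across genes with the footprint level of the partner (Spearman rho 0.36) more than with that of the gene itself (0.210), a difference of 0.150 (bootstrap interval 0.102 to 0.196). Tsix, antisense to Xist, had 2.28 and 9.43 CPM in WT and KO RNA-seq. Without these overlapping genes 86 genes were called in RNA-seq. The count was 242 without WT replicate 1 and 73 without KO replicate 1, and 13 of the 23 named genes called lost the call when some library was left out.

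Translational efficiency compared the footprint change with the RNA-seq change of the same gene. Relative to RNA-seq, footprints fell on Mettl5 (-2.35, SE 0.40, adjusted p = 0.00713) and rose on Apoe (3.11, SE 0.48, adjusted p = 0.00557), Pou5f1 (2.33, SE 0.47, adjusted p = 0.0146) and 9 of 44 ribosomal protein genes. Of 1458 genes tested, 135 were called, 69 higher and 66 lower, and 356 had an unadjusted p below 0.05. Of the 135, 59 were also called in RNA-seq and 10 in footprints. Of 44 ribosomal protein genes, 9 rose (19 adjusted over the list alone), Rpl32 (2.24) and Rpl3 (1.81) among them, with a median of 1.01 (camera adjusted p = 1.82e-06; adjusted p = 0.615 with an estimated correlation). In footprints alone the median of all 79 ribosomal protein genes was 0.07. Pou5f1 had only 17 and 18 RNA-seq counts in WT and 3 and 4 in KO, and Apoe 18 and 24 against 3 and 8. Footprints on Pou5f1 alone did not pass the test (0.30, adjusted p = 0.36), while those on Apoe rose (1.46). The strand setting behind the RNA-seq counts is not given. If they came from the opposite strand, these efficiencies would not measure translation.

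Further increases were those of Itpripl1 (1.98), Samd8 (1.70), Tmf1 (1.63), Pigm (1.59) and H2-Q4 (1.55). Rprl3 (2.16) and Rn45s (3.4, adjusted p = 0.0196) rose too, but both are noncoding RNAs, so their values do not measure translation. Tdgf1 (2.95), Eef1a1 (1.31) and the ATP synthase subunit gene Atp5a1 (1.84) rose as well. Gfer (-1.55), Wdr92 (-1.52), Abt1 (-1.38), Orc3 (-1.26), Mrps25 (-1.25), the termination factor gene Gspt1 (-1.54) and the cap methyltransferase gene Pcif1 (-2.51) fell. Trmt112 (-0.67, adjusted p = 0.515) and Nanog (0.89, adjusted p = 0.212) did not pass the test, and the other 12 lists were not called (camera adjusted p 0.129 to 0.942). These values rest on the low counts of the RNA-seq tables, and 22 of the 24 named genes called lost the call when some library was left out. The count was 57 without KO RNA-seq replicate 1, 75 without KO RNA-seq replicate 2, 69 and 83 without WT Ribo-seq replicates 1 and 2, and 40 and 18 without KO Ribo-seq replicates 1 and 2.

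Fold changes of the RNA-seq table entries and of the footprints under the same names had a correlation near 0 across the 1458 genes tested in both. Pearson's r was 0.0221 (bootstrap interval -0.115 to 0.141) and Spearman's rho 0.0575. Higher in both were 3 genes, Krt8 (4.26 in RNA-seq, 2.01 in footprints), Spon1 (3.0 and 2.89), a secreted matrix protein gene, and Tagln (3.86 and 1.84), against 0.757 for independent lists (Fisher's exact p = 0.0373, two-sided). Lower in both were 0 genes, against 0.240 for independent lists (p = 1, Fisher's exact test). Ftl1, the ferritin light chain gene, fell in RNA-seq (-1.53) and rose in footprints (0.83).

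**Figure D5:**
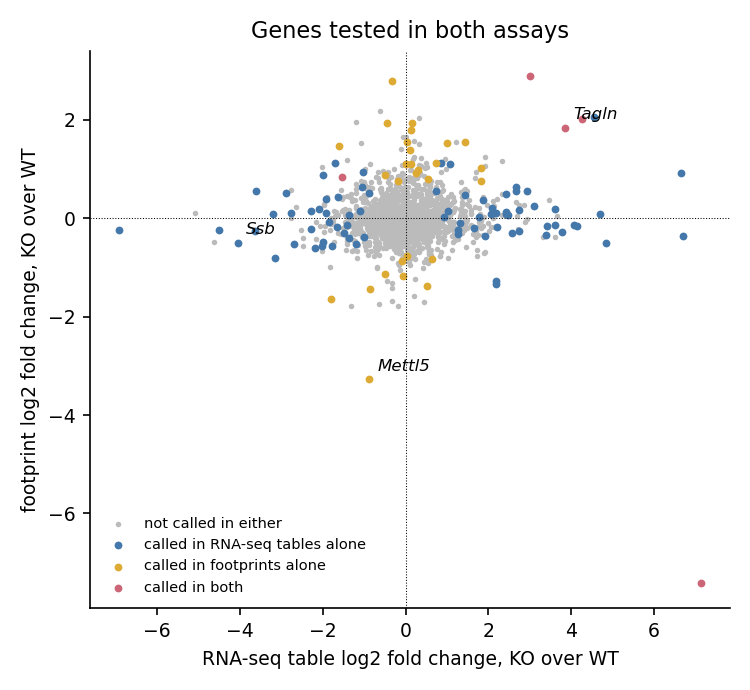
Log2 fold change, KO over WT, in the RNA-seq tables (x axis) and in footprints (y axis) for the 1458 genes tested in both; colours mark the assay in which a gene was called. Mettl5 lies at -0.88 and -3.27, Ssb at -4.05 and -0.50, and the point at the lower right is the clone gene Gm3448, with 0 counts in 1 genotype in each assay.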

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

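The share and fold change tests for the RNA-seq tables were chosen after the result was seen; the strand test was set before its result. A test of the difference itself, the interaction of assay and genotype, found 135 genes whose KO to WT change differed between footprints and RNA-seq. Mettl5 was among them, with a footprint minus RNA-seq log2 fold change of -2.35, and so was its opposite-strand neighbour Ssb, with 3.63.

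The pattern behind both is that abundant mRNAs were nearly empty in the RNA-seq tables and that at the Mettl5 locus Ssb fell in RNA-seq by -4.05 log2 in KO, while Mettl5, at -0.88, was lower without passing the test. Shallow sequencing alone is argued against by the share of the 100 genes with most footprints. With Rn45s left out of the totals, that share was 27.7 times larger in footprints than in RNA-seq. The range over pairs of libraries was 22.5 to 37.1. Genomic DNA in the RNA-seq libraries stays open, because 92.5% of the 133 called genes changed by more than 1 on the log2 scale, but a share among called genes decides nothing where 15.2% of simulated 2-fold changes were recovered. Counting on the opposite strand is a candidate explanation, since RNA-seq levels followed the partner's footprints more than the gene's own by 0.150 in Spearman's rho (0.102 to 0.196), and by 0.331 (0.252 to 0.413) over the 893 overlaps of at least 500 bp. For fold changes over 367 pairs the difference was 0.0421 (-0.0885 to 0.174), so changes do not decide it, and if the counts came from the other strand, the RNA-seq calls, such as those of Rtl1, Tmf1, Tdgf1 and the ribosomal protein list, would not be changes of the named transcripts, the correlation with footprints would compare different transcripts, and the translational efficiencies would not measure translation.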

How the results depend on the processing

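Mettl5 kept its footprint call under all 16 alternatives (log2 fold change -3.44 to -3.02) and its translational efficiency call under all 20 (-2.55 to -1.87). No named gene changed sign where the main fit or the alternative called it. Sign changes of genes called in neither were not counted. The correlation of RNA-seq and footprint changes stayed between -0.00945 and 0.0776. Called genes in RNA-seq (133) were 76 with a mean count of at least 50 (43.4% higher, against 57.9%), 75 with DESeq2, 57 with limma-voom, 39 with limma on log2(TPM + 1) (74.4% higher), 261 in the joint fit, 86 without genes overlapping an opposite-strand gene, and 73 to 242 when a library was left out. Called genes in footprints (301, 74.8% higher) were 1110 without the filter (63.6% higher), 186 with a mean count of at least 50, 114 with limma on log2(TPM + 1), 181 against a 1.2-fold change, 467 in the joint fit and 189 to 761 when a library was left out; with the length trend removed 64.3% of calls were higher. Called genes in translational efficiency (135, 51.1% higher) were 17 with a mean count of at least 50, 72 with limma on log2(TPM + 1) (18.1% higher), 86 without overlapping genes, and 18 to 154 when a library was left out; without the filter 37.3% were higher, without any 1 RNA-seq library 72.0% to 73.7%, and without KO Ribo-seq replicate 2 27.8%. The cause of these shifts was not tested, except that fewer genes were tested where a filter or overlap removed them. With 1 library left in a group, it was assumed to vary like the others.

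With the replicate number as a block, 2960 genes were called in footprints (1566 higher, 1394 lower, 52.9% higher), including all 301. In RNA-seq the block gave 155 calls and in translational efficiency 160. Deviations from the group means of same-numbered libraries correlated by 0.424 in footprints and 0.0533 in RNA-seq, over 2 pairs each, and the labels do not say that a number marks a shared day. The names of the Ribo-seq tables carry a tag shared by same-numbered WT and KO libraries; if it marks a shared day, the block is the better fit and the 301 calls are too few. Of the called lists (1 in RNA-seq, 14 in footprints, 1 in translational efficiency), 0 were kept with an estimated correlation in any comparison. With fry, 2, 0 and 3 lists were called. With a mean count of at least 50, 0 lists were called in RNA-seq and in translational efficiency, where 2 could be tested. In footprints 11 lists were called with that filter, 10 of them among the 14. Neuroectoderm was gained, and the mesoderm median was -0.58. The mesoderm (camera adjusted p = 0.0536), germline (0.125) and G2 and M (0.0704) lists lost their calls. With the block, the histone list was also called. Leaving out each library kept 6 of the 14 footprint lists throughout (endoderm, ribosome biogenesis, imprinted, formative, mesoderm and fibroblast). In simulated counts, 15.2% of 2-fold changes were recovered in RNA-seq, 14.8% in translational efficiency and 44.0% in footprints.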

Other observations

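The interferon list, the RNA-seq test over 3 chromosomes together and both cell type tests were chosen after the results were seen. Some interferon-induced genes and genes of class I antigen presentation rose in KO footprints. Of 42 tested members of a textbook list, 10 rose and 0 fell (16 and 0 adjusted over the list alone). The list was chosen after members were seen to rise, so no test of it as a group is given. The guanylate-binding protein gene Gbp2 rose from 7.60 to 42.9 CPM (log2 fold change 2.53, adjusted p = 0.00238), the immunoproteasome subunit gene Psmb8 from 0.691 to 7.69 CPM (3.49, adjusted p = 0.00907) and the peptide transporter gene Tap2 from 2.75 to 11.7 CPM (2.06, adjusted p = 0.0161). Isg15 (2.78), Erap1 (1.32), Gbp3 (2.36), Gbp7 (2.53), Gbp2b (2.77), Tapbp (0.88) and Ifitm1 (0.86) rose too, while B2m (0.65), Tap1 (1.53), Psmb9 (0.44), H2-K1 (0.16) and H2-D1 (-0.26) did not pass the test. The median of the list was 0.20.

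Footprints of genes on chromosomes 6, 8 and 11 were lower as a group in KO. The shift spanned chromosome 6, with medians of -0.35, -0.42 and -0.38 in its 3 successive parts, and each KO library lay below each WT library by -0.43 to -0.40 on chromosome 6, while the WT libraries differed by 0.02 and the KO libraries by -0.01. GC content, length or level of the genes is argued against, because the chromosome 6 median stayed at -0.42 relative to the other chromosomes after loess trends on these were removed (-0.46 to -0.39). A few strongly changed genes are argued against by the 83.0% of chromosome 6 genes with negative fold changes. The difference over the 505 genes not called was -0.42 (-0.45 to -0.38), but leaving out the few called genes could hardly move a median. A chromosome copy number difference between the lines is a candidate explanation, which cannot be told apart from the genotype here. In the separate RNA-seq libraries the chromosome 6 difference was -0.15 (-0.33 to 0.03). Those of chromosomes 8 and 11 were -0.16 (-0.36 to -0.03) and -0.06 (-0.16 to 0.11), and that of the 3 chromosomes together -0.11 (-0.19 to -0.03). RNA-seq medians of chromosomes 13 (-0.12) and X (-0.10) lay near that of chromosome 6 (-0.12), while their footprint medians were 0.07 and 0.03. The RNA-seq values thus do not single out chromosomes 6, 8 and 11. Loss of 1 of 3 copies would give -0.58, and the chromosome 6 difference in footprints was -0.44 (-0.47 to -0.40). A gain in part of the WT cells, or an effect of METTL5 loss, therefore stays open and was not tested.

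In KO footprints, camera called the fibroblast list higher, with 3 of 15 members called, and the endoderm list lower, with 4 of 16 called lower; neither call was kept (adjusted p = 0.559 with an estimated correlation for both). A smaller share of stem cells with a larger share of all other cell types would raise both lists. The endoderm list had a median of -1.22 (quartiles -1.58 and -0.42) beside the fibroblast median of 1.80. Endoderm markers thus did not share in the rise. This contrast is the pattern to be explained, so it is no separate test of that explanation and decides nothing. A larger share of feeder or other fibroblasts might raise the fibroblast markers. Col1a1 (70.9 and 23.9 CPM) and Col5a2 (9.36 and 2.26 CPM) both differed between the WT libraries, and in KO they changed apart by 2.59 log2 (1.02 to 4.15). This lies beyond the bound of 2 standard errors first set for a single source, but the pair was picked after its values were seen and neither gene was called, so it decides nothing, a verdict reached after the value was known. More fibroblasts and altered expression in the stem cells cannot be told apart. Of the abundant fibroblast products, Col1a1 had a log2 fold change of 2.37 (adjusted p = 0.132), Fn1 0.57 and Vim 0.55, none of them called, and Sparc, in the endoderm list, -0.42.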
